A study of Homo sapiens with 12 samples.

How the data were processed

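RNA from 12 cultures of cancer cell lines was hybridised to 3′ expression microarrays. The cells were A549, a human lung adenocarcinoma line, and cells labelled LoVo, a human colorectal adenocarcinoma line. Each was infected with a lentivirus carrying uc.339, a transcribed ultraconserved region, or with the empty vector, at a multiplicity of infection of 10. Per the labels' protocols, infected cells were sorted for green fluorescent protein, and RNA was extracted with TRIzol 48 hours after plating and labelled with biotin. The sample titles put 3 arrays in each of 4 groups. A description of the LoVo arrays and the series text each write another number for the region once. This was read as a slip, because the titles and the protocol give uc.339.

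The deposited values are log2 expression values, 1 per probe set and array, made by the authors with robust multi-array averaging (RMA) per the submitters' processing notes. The version of RMA is not given in the sources used here. RMA subtracts background, forces all arrays to a shared distribution and summarises the probes of a probe set, so a change shared by most genes would be removed. The table holds 54675 probe sets, and 62 control probe sets were left out of the gene tests. The probe table listed 1 gene symbol for 41091 probe sets, several for 1801 and none for 11721. Of the probe sets with 1 symbol, the one with the highest mean over the 12 arrays stood for its gene, which gave 19775 genes, of which 10523 had more than 1 probe set. Gene identifiers were looked up in the gene table of assembly GRCh38.p14, used for names only; 19735 were found and 0 symbols changed. Each column of the table carried the identifier of its sample. Array medians lay between 5.53 and 5.61, and values between 2.12 and 14.93. No depth applies to arrays, whose number limits the precision.

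A limma model (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with 4 group means was fitted to all 12 arrays, with no filter on dim probe sets. Contrasts were uc.339 minus empty vector in each line, the difference between these contrasts, and the empty-vector arrays of one line against those of the other. P-values were adjusted by Benjamini-Hochberg over all genes and called at an adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists, and again with an estimated correlation. Calls rest on camera, which compares a list with the other genes. The directional fry test of limma, planned beside it, asks whether a list's own members changed. Its p-values were not adjusted over the lists. The 22 pathway lists covered G1/S and replication, CDK inhibitors and pocket proteins, G2/M and mitosis, mesenchymal and invasion genes, epithelial genes, p53 targets, apoptosis regulators, interferon-stimulated genes, NF-kB and inflammatory genes, the integrated stress response, ER chaperones and the unfolded protein response, heat shock proteins, hypoxia and glycolysis, cholesterol synthesis, NRF2 targets, Wnt targets, immediate early and MAPK feedback genes, TGF-beta and YAP targets, microRNA pathway proteins, cytosolic ribosomal proteins, oxidative phosphorylation and housekeeping genes. The other 5 held markers of intestinal epithelium, lung epithelium, immune cells, fibroblasts and endothelium. Tests of single values with 3 arrays against 3 were two-sided exact permutation tests, whose smallest possible p is 0.1. Tables were handled in Python 3.11.15 with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.

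The groups, contrasts, thresholds, lists, alternatives and the rule for named genes were set before the data were examined, except where stated. In each line the rule named the 10 largest rises and the 10 largest falls among called genes whose 3 uc.339 arrays all lay on 1 side of the 3 empty-vector arrays. It named the 5 highest and 5 lowest of the genes called with the same sign in both lines, by the smaller change, and the 5 largest differences between the lines in each direction. It also named up to 4 members with the smallest p in each list described, and CCNE2 always. Members were named for lists that passed the test, a narrowing made after the data were seen; other lists are given as counts. Other probe sets of a named gene are given where 1 of them read the opposite sign or under 10% of the change, a limit chosen after the data were seen. RMA values carry no detection calls. As a guide, also chosen after the data were seen, a group mean is called dim at or under the 90th percentile of 20 immune and endothelial markers in that group (6.02 to 6.34 log2). Background differs between probe sets, so a dim level can still change, but sizes measured to or from it are limited. 1 gene named by the rule is not reported here.

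On simulated A549 data of 19775 genes, with 50 genes changed at each size, the model recovered 20% of changes of 0.25 log2, 68% of 0.5, 96% of 1 and 100% of 2. It called 150 genes, of which 5.33% had not been changed, and 0 genes in simulated LoVo arrays with none changed. With 1 list shifted by 0.2 log2, 1 of 27 lists was called. The noise was drawn independently for each gene, while real genes vary together, so the simulation does not check false calls under shared variation.

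The series text ties replicate numbers to experiments, so same-numbered arrays may be pairs. The main fit did not use the pairs, and fits with the number as a block were alternatives. As a check, deviations from the group means of same-numbered uc.339 and empty-vector arrays correlated at 0.04, 0.26 and 0.25 in A549 and at -0.03, -0.17 and -0.36 in LoVo. Between the lines, same-numbered uc.339 arrays correlated at -0.0005, 0.31 and 0.33, and empty-vector arrays at 0.04, -0.10 and -0.16. The first component of these deviations held 31.1% of their variance. Its absolute correlation with the arrays' interquartile range was 0.891, so the lines may share some variation between arrays. The labels do not say whether replicates came from separate infections, so p-values measure the spread between these arrays, which may be technical. Other alternatives were centring, cyclic loess, the brighter genes, averaged or separate probe sets, single-line fits, trend and robust eBayes, array weights, stricter thresholds and leaving out each array. Covariates for each array's interquartile range and for its ACTB 3′ minus 5′ difference were added after the data were seen. Binding of microRNAs to uc.339 was not analysed here.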

Results

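Expression profiles were compared between cells carrying uc.339 and cells carrying an empty vector, in A549 and in cells labelled LoVo, with 3 arrays in each of the 4 groups. The study's title concerns uc.339 as a trap for tumour suppressor microRNAs. CCNE2, which encodes cyclin E2, was known before the data were examined as the gene that the study ties to uc.339. Across probe sets, arrays of the same group correlated at 0.994 to 0.997 (12 pairs). Arrays of the same line but other arm correlated at 0.989 to 0.997 (18 pairs), and arrays of different lines at 0.893 to 0.909 (36 pairs). No pair of arrays held identical values.

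The first comparison set the empty-vector arrays of the lines side by side. Epithelial and matrix genes differed between them in both directions. CDH1, the epithelial cadherin, read 10.45 ± 0.07 log2 units in A549 and 3.88 ± 0.27 in the arrays labelled LoVo (mean ± SD, n = 3 each). DSP, a desmosome protein, read 11.24 ± 0.07 and 3.88 ± 0.12, and CEACAM6, a carcinoembryonic antigen relative, 12.43 and 4.76. POSTN, a matrix protein, read 3.36 ± 0.25 in A549 and 14.52 ± 0.04 in the arrays labelled LoVo, and the collagen gene COL3A1 and the collagenase gene MMP1 were also higher there, at 12.28 and 11.18 against 4.65 and 3.00. VIM, an intermediate filament gene of mesenchymal cells, read 14.71 against 13.24. The matrix genes FN1, fibronectin, and TGFBI were lower there, at 5.86 and 5.53 against 12.43 and 12.42 in A549. The lower levels of CDH1, DSP, CEACAM6, POSTN, COL3A1, MMP1, FN1 and TGFBI were dim by the limit given with the processing, so no fold is given for them. Of the 14 intestinal epithelium markers, 0 were at least 2-fold higher in the arrays labelled LoVo and 4 were at least 2-fold lower, while 4 passed as higher and 5 as lower at any size (median 0.136). The intestinal transcription factor gene CDX2 read 5.40 against 5.20 and VIL1, a brush border protein gene, 5.77 against 5.56, all dim. Of the 21 epithelial genes, 0 were at least 2-fold higher and 8 at least 2-fold lower, while KRT19 and the tight junction gene OCLN were higher, at 11.08 and 10.32 against 10.31 and 9.56. All 21 NRF2 targets, genes of the oxidant response, were higher in A549, 20 of them at least 2-fold, with AKR1B10 at 14.58 against 4.15. Of the 10 fibroblast markers, 4 were at least 2-fold higher in the arrays labelled LoVo, as was 1 of 11 lung epithelium markers, with 1 lower; of 11 immune cell markers 0 were higher and 1 was lower by that margin, and of 9 endothelial markers 0 differed by it. In the 23 mesenchymal and invasion genes, 6 were at least 2-fold higher and 7 at least 2-fold lower.

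Across all genes, limma with Benjamini-Hochberg adjustment called 12584 of 19775 genes different between the lines, 8353 of them (66.4%) higher in the arrays labelled LoVo. With cyclic loess the share was 53.8% of 11139 genes, and the median over all genes moved from 0.18 to 0.06 log2. The counts of intestinal markers were 0 and 4 under every scaling. Because 0 of the 14 intestinal markers were higher by that margin, these are called the arrays labelled LoVo, and each direction given for LoVo holds for cells under that label.

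**Figure D1:**
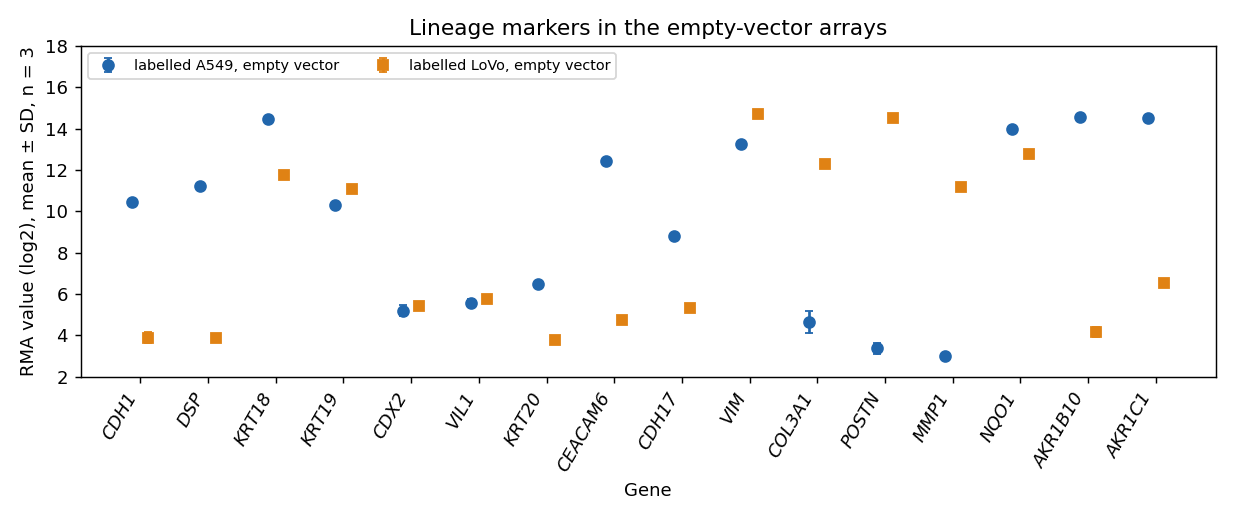
Levels of marker genes (log2 expression, mean ± SD) in the empty-vector arrays of A549 and in those labelled LoVo, n = 3 each. CDH1 read 10.45 in A549 and 3.88 in the arrays labelled LoVo, and POSTN 3.36 and 14.52.

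In A549, the largest falls with uc.339 were in TCN1 and FCGBP. TCN1, a vitamin B12 binding protein of secretions, fell by 2.28 ± 0.11 log2 units (SE), from 7.78 ± 0.08 to 5.50 ± 0.11 (SD, n = 3; adjusted p = 1.48e-06, limma). FCGBP, a mucus protein, fell by 2.21 ± 0.11 and CEACAM6 by 1.85 ± 0.12. The gel-forming mucin gene MUC5AC fell by 2.00 ± 0.27 (adjusted p = 0.000931), with its other probe sets between -2.09 and 0.26, and MUC5B fell by 1.74 ± 0.15, with its other probe set at -0.17. C9orf152 fell by 2.05, ST6GALNAC1, a sialyltransferase of O-linked glycans, fell by 1.89, TNFSF15, a tumour necrosis factor family ligand, fell by 1.77, SMIM31 fell by 1.74 and CDH17, a cadherin of intestinal epithelium, fell by 1.71. Among the rises, ANKRD29 gained 1.35 ± 0.16 (adjusted p = 0.00042), SPOCK1, a matrix proteoglycan, 1.32 ± 0.13, KCNMA1, a potassium channel gene, 1.24 (other probe sets 0.01 to 0.18) and BCAT1, an enzyme of branched-chain amino acid use, 1.20 ± 0.10 (other probe sets 0.03 to 1.01). C1orf21 rose by 1.18 (other probe sets 0.03 to 0.62), CA8 by 1.18, CLMP by 1.17, NPR3, a natriuretic peptide receptor, by 1.12, IGFBP7 by 1.11 (other probe sets 0.11 to 1.07) and GFRA1 by 1.08. The levels of C9orf152 and SPOCK1 were dim in both arms, the falls of TCN1 and SMIM31 ended at a dim level and the rises of CLMP and GFRA1 began at one. In all, 2322 genes passed, 1097 up and 1225 down, with a median size of 0.36 log2; 88 changed at least 2-fold, 12 up and 76 down.

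Proliferation genes rose in A549. Of 26 G2/M and mitosis genes, 11 rose and 0 fell (21 and 0 adjusted over the list alone), with a list median of 0.24 (adjusted p = 8.22e-09, camera; adjusted p = 0.0205 with an estimated correlation). BUB1, a spindle checkpoint kinase, rose by 0.49 (other probe sets -0.01 to 0.88), CENPE by 0.39, CDC25C by 0.33 and CCNB1, cyclin B1, by 0.30. Of 32 G1/S and replication genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.10, adjusted p = 0.00694, and adjusted p = 0.044 with an estimated correlation). MCM4 and MCM6, parts of the replicative helicase, rose by 0.41 and 0.32, RRM2 by 0.35 and GINS2 by 0.31. Other probe sets of MCM4 read -0.15 to 0.37 and those of GINS2 -0.06 to 0.02, and averaging all probe sets ended both calls (adjusted p = 0.228 and adjusted p = 0.345).

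ER chaperone, inflammatory, intestinal, epithelial and immediate early lists moved down in A549. Of 19 ER chaperone and unfolded protein response genes, 0 rose and 7 fell (0 and 9 adjusted over the list alone; median -0.15, adjusted p = 1.06e-05, and adjusted p = 0.0205 with an estimated correlation). XBP1, a transcription factor of secretory cells, fell by 0.49, DNAJC3 by 0.37, CRELD2 by 0.24 and PDIA4 by 0.23. Of 21 NF-kB and inflammatory genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone; median -0.07, adjusted p = 0.0243, but adjusted p = 0.0972 with an estimated correlation). PTGS2, cyclooxygenase, fell by 1.02, CXCL3 by 0.59 and CXCL5 by 0.44, and NFKBIA read -0.16 (other probe set 0.08) without passing. Of 14 intestinal epithelium markers, CEACAM6, CDH17, KRT20 (-1.31) and MUC13 (-1.05) fell, the same 4 adjusted over the list alone, and 0 rose (median -0.04, mean -0.41; adjusted p = 0.0243, but adjusted p = 0.288 with an estimated correlation). The fall of KRT20 ended at a dim level. Of 21 epithelial genes, 0 rose and 3 fell, as adjusted over the list alone (median -0.08, adjusted p = 0.0302, but adjusted p = 0.105 with an estimated correlation). These were KRT19 (-1.12, its other probe set -0.07), JUP (-0.47) and KRT8 (-0.39), with EPCAM at -0.28 and not passing. Of 23 immediate early and MAPK feedback genes, 3 rose and 8 fell (5 and 9 adjusted over the list alone; median -0.11, adjusted p = 0.0302, but adjusted p = 0.125 with an estimated correlation). FOS fell by 0.77, to a dim level, and ETV5 by 0.59 (other probe sets -0.41 to 0.05), while the phosphatase genes DUSP5 and DUSP1 rose by 0.65 and 0.42. Testing the brighter genes alone ended the immediate early call (adjusted p = 0.0835), and averaging probe sets ended the NF-kB call (adjusted p = 0.114). The interquartile range as a covariate, added after the data were seen, ended the G1/S, NF-kB, epithelial and immediate early calls (adjusted p from 0.073 to 0.107). The list medians did not shrink with it, at 0.152, -0.159, -0.088 and -0.133 against 0.101, -0.070, -0.081 and -0.113 without it. The interquartile range was itself lower with uc.339 in A549, at 3.45 ± 0.06 against 3.52 ± 0.02 with the empty vector (SD, n = 3, exact permutation p = 0.1). The nearest arrays of the 2 arms read 3.499 and 3.5, so this covariate was partly tied to the arm in A549.

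The A549 arms also differed in a control of transcript integrity. The ACTB 3′ minus 5′ control difference was 1.21 ± 0.09 with uc.339 and 1.98 ± 0.05 with the empty vector (SD, n = 3; exact permutation p = 0.1, the smallest possible), and the GAPDH difference 0.21 and 0.34 (exact p = 0.1). With the ACTB difference as a covariate, added after the data were seen, limma called 0 genes, while 2004 had an unadjusted p under 0.05 and 91.5% of the 2322 genes had the same sign. The median SE of those genes rose from 0.0756 to 0.298, and of the 7 lists the G2/M and mitosis list still passed (adjusted p = 0.000766). With replicate number as a block within each line, 1382 genes passed, 1318 of them among the 2322, and CRELD2, CXCL5, JUP and PDIA4 no longer passed (adjusted p from 0.0502 to 0.107). Without uc.339 replicate 1 or 2 the count was 1449 or 1460, and without empty-vector replicate 1 or 3 it was 1354 or 1408.

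**Figure D2:**
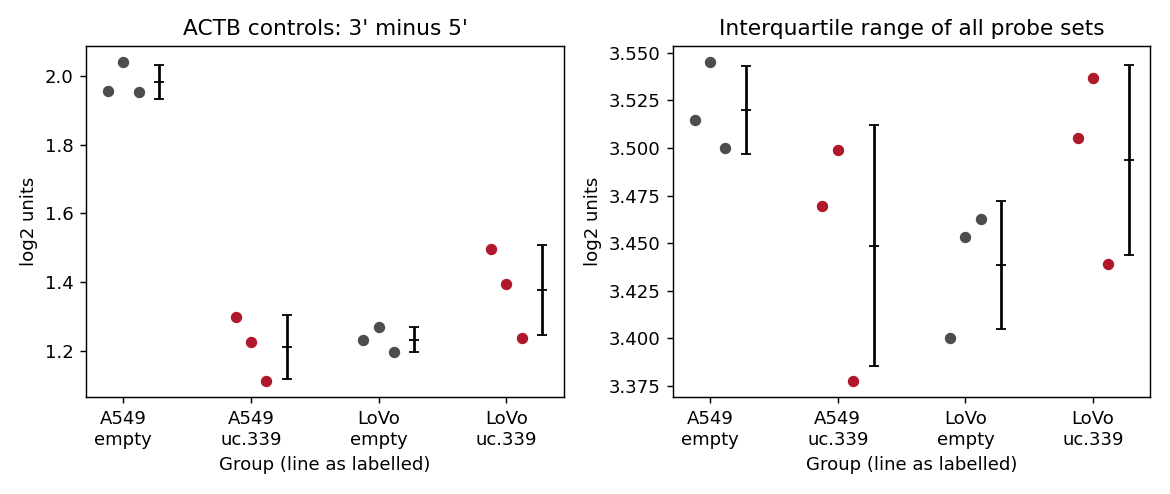
ACTB control 3′ minus 5′ difference and interquartile range of all probe sets (both in log2 units) of the 12 arrays by group, with points for arrays and bars for mean ± SD; the axes do not start at 0. The ACTB difference was 1.21 with uc.339 and 1.98 with the empty vector in A549.

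In the arrays labelled LoVo, the largest falls were in other genes. ALDH1A1, a retinaldehyde dehydrogenase, fell by 2.69 ± 0.19 log2 units, from 6.30 ± 0.17 to 3.62 ± 0.52 (SD, n = 3; adjusted p = 1.88e-05, limma). EREG and BTC, ligands of the EGF receptor, fell by 2.66 ± 0.17 and 1.27, and ANXA1, a phospholipid binding protein, by 2.41 ± 0.09 (adjusted p = 1.32e-07). The other probe sets of EREG and ANXA1 read -0.03 and -0.11. The collagen gene COL1A2 fell by 1.77 and COL11A1 fell by 1.46. EPAS1, a hypoxia-inducible factor, fell by 1.38 (other probe sets -0.20 to -0.12), ADGRL4 by 1.37, CEACAM1 by 1.37 (other probe sets -0.24 to -0.0005) and S1PR1, a sphingolipid receptor, by 1.36 (adjusted p = 0.0129). TCF4, a basic helix-loop-helix transcription factor, rose by 2.28 ± 0.11 (adjusted p = 5.29e-07; other probe sets -0.15 to 1.48), EPHA7, an ephrin receptor, by 2.13 ± 0.11 and BASP1 by 1.93 ± 0.06, although its other probe set read -0.27. CA2, carbonic anhydrase, rose by 1.78, CRIM1 by 1.63, LRRC4C by 1.33 (other probe set 0.09), SLC27A6 by 1.30, TYRP1, a melanosome protein, by 1.28 and MACROD2 by 1.21 (other probe sets -0.14 to 0.31). The levels of EREG, BTC, CRIM1, LRRC4C, TYRP1 and MACROD2 were dim in both arms. The falls of ALDH1A1, ANXA1, COL1A2, COL11A1, ADGRL4 and CEACAM1 ended at a dim level, and the rises of TCF4 and CA2 began at one. In all, 412 genes passed, 164 up and 248 down, with a median size of 0.47 log2; 28 changed at least 2-fold, 14 each way.

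Integrated stress response, immediate early and epithelial lists moved down in the arrays labelled LoVo. Of 22 integrated stress response genes, 0 rose and 9 fell (0 and 17 adjusted over the list alone; median -0.30, adjusted p = 6.23e-11, camera, and adjusted p = 0.00547 with an estimated correlation). ATF3, a stress-induced transcription factor, fell by 0.70, TRIB3 by 0.50, CEBPB by 0.39 and SLC7A11, the cystine transporter, by 0.34, a call that ended when its probe sets were averaged (adjusted p = 0.0762). Of 23 immediate early and MAPK feedback genes, 0 rose and 4 fell (1 and 9 adjusted over the list alone; median -0.17, adjusted p = 0.0193, but adjusted p = 0.115 with an estimated correlation): PHLDA1 by 0.81, ATF3, JUN by 0.55 and DUSP5 by 0.48. Of 21 epithelial genes, 1 rose and 3 fell (1 and 7 adjusted over the list alone; median -0.15, adjusted p = 0.011, but adjusted p = 0.073 with an estimated correlation). KRT19 fell by 1.06, KRT8 by 0.90 and KRT18 by 0.37, and EPCAM, an epithelial adhesion molecule, rose by 0.81. Most members of this list were dim in both arms, which limits what its median shows. These were CDH1, CLDN1, CLDN3, CLDN4, CLDN7, DSP, ELF3, ESRP1, GRHL2, MAL2 and RAB25.

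Proliferation and chaperone lists moved up in the arrays labelled LoVo by small amounts. Of 32 G1/S and replication genes, 3 rose and 0 fell (3 and 1 adjusted over the list alone; median 0.08, adjusted p = 0.0129, but adjusted p = 0.073 with an estimated correlation). These were CDC6 (0.36), MCM10 (0.34) and GINS1 (0.26), while TK1 read -0.27 without passing. Of 26 G2/M and mitosis genes, 0 passed in either direction at an adjusted p (4 up and 0 down adjusted over the list alone; median 0.07, adjusted p = 0.011, but adjusted p = 0.188 with an estimated correlation). TOP2A read 0.29 (other probe sets -0.01 to 0.43), BUB1 0.24 (other probe sets -0.03 to 0.67), DLGAP5 0.21 and AURKA 0.20, none passing. Of 12 heat shock proteins, DNAJA1 rose by 0.33 and 0 fell (2 up and 0 down adjusted over the list alone; median 0.11, adjusted p = 0.0129, but adjusted p = 0.115 with an estimated correlation). HSPA4 read 0.30, HSPA4L 0.25 and HSPE1 0.16, none passing. TOP2A, BUB1, DLGAP5, AURKA, TK1, HSPA4 and HSPE1 did pass in the brighter genes, with trend and robust eBayes and with array weights (adjusted p from 0.0112 to 0.0444). HSPA4L passed with array weights (adjusted p = 0.0474). Cyclic loess ended the calls of the G1/S (adjusted p = 0.153) and G2/M lists (adjusted p = 0.141). Testing the brighter genes alone ended those of the G1/S (adjusted p = 0.139), G2/M (adjusted p = 0.0961), heat shock (adjusted p = 0.0601) and epithelial lists (adjusted p = 0.0757).

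The count of LoVo genes moved with single arrays. Without uc.339 replicate 3 it was 1347, and only the integrated stress response list then passed; without uc.339 replicate 1 or 2 it was 140 or 161, without empty-vector replicate 1 or 2 it was 146 or 139, and without A549 empty-vector replicate 1 it was 257. With replicate number as a block within each line 167 genes passed, 155 of them among the 412, and the immediate early list did not (adjusted p = 0.104). That list also lost its call with array weights, averaged probe sets or the arrays of that line alone (adjusted p from 0.0801 to 0.123). Under that block ADD2, CDC6, CSTA, DNAJA1, FRMD6, GINS1, IFITM3, IL1RAP, KRT18, MCM10, S1PR1 and SLC7A11 no longer passed (adjusted p from 0.0547 to 0.121), and with a block over both lines TOP2A passed (adjusted p = 0.0386). The ACTB difference averaged 1.38 with uc.339 and 1.23 with the empty vector here (exact permutation p = 0.2, n = 3), and the uc.339 array was the higher in all 3 same-numbered pairs, by 0.266, 0.125 and 0.041. With it as a covariate 110 genes passed, and all 412 kept their sign. CAVIN2, CEBPB and the genes the block ended, except S1PR1 and SLC7A11, no longer passed (adjusted p from 0.0524 to 0.366).

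**Figure D3:**
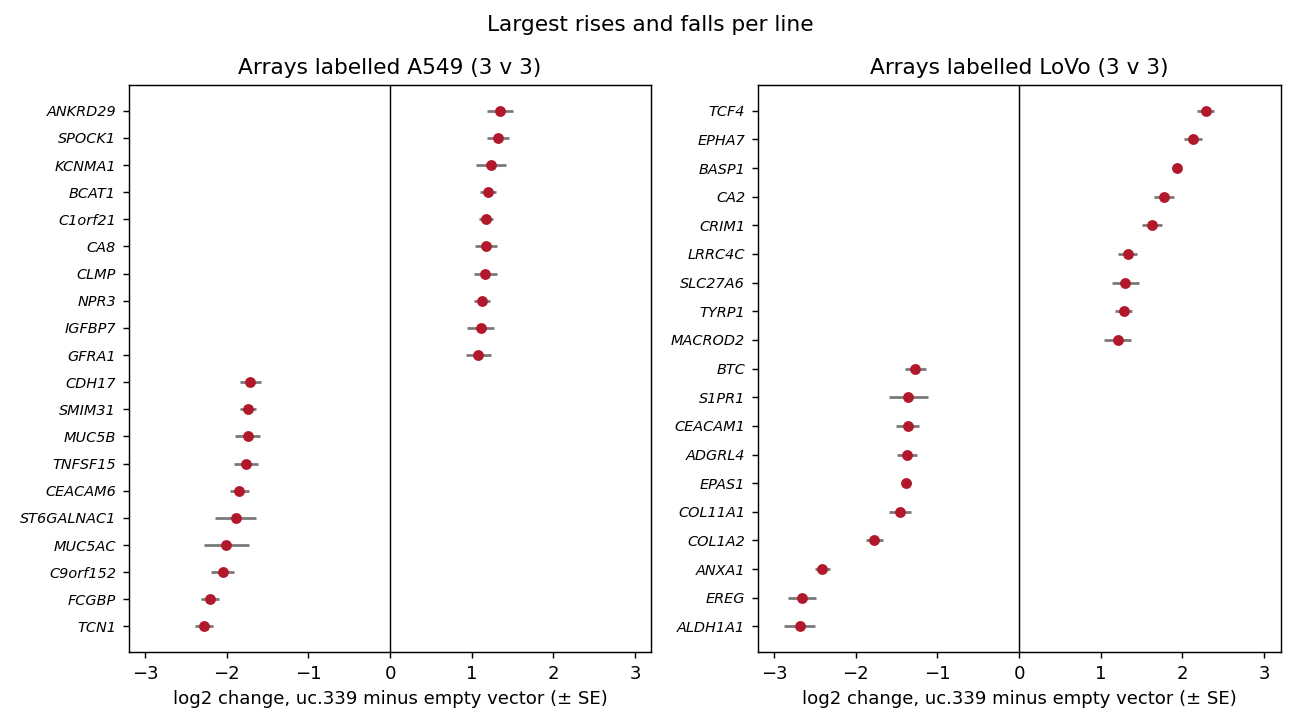
Changes with uc.339 (log2, bars are ± SE) of genes with the largest rises and falls in A549 and in the arrays labelled LoVo, n = 3 arrays per group. TCN1 fell by 2.28 in A549, and TCF4 rose by 2.28 in the arrays labelled LoVo.

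The remaining lists did not pass camera in A549 (20 lists, adjusted p from 0.0825 to 0.985) or in the arrays labelled LoVo (21 lists, adjusted p from 0.0898 to 0.997). For them the unadjusted p from fry ran from 0.00049 (TGF-beta and YAP targets) to 0.953 (fibroblast markers) in A549. In the arrays labelled LoVo it ran from 0.000406 (TGF-beta and YAP targets) to 0.674 (endothelial markers). A list that did not pass camera may thus still hold members that changed. Over these lists together, 31 members rose and 26 fell in A549 (41 and 38 adjusted over the list alone), and 7 rose and 16 fell in the arrays labelled LoVo (22 and 26). The integrated stress response had 6 of 22 genes rising and 0 falling in A549 (9 and 1 adjusted over the list alone). In A549, members rising and falling numbered 2 and 3 of 23 mesenchymal and invasion genes, 2 and 2 of 22 p53 targets, 2 and 2 of 18 apoptosis regulators, 2 and 3 of 30 interferon-stimulated genes, 3 and 1 of 12 heat shock proteins and 3 and 5 of 25 hypoxia and glycolysis genes. They numbered 1 and 1 of 17 cholesterol synthesis genes, 3 and 2 of 21 NRF2 targets, 0 and 3 of 16 Wnt targets, 2 and 1 of 16 TGF-beta and YAP targets and 1 and 3 of 13 microRNA pathway proteins. In the arrays labelled LoVo they numbered 1 and 2 of the mesenchymal genes, 2 and 3 of the p53 targets, 0 and 2 of the interferon-stimulated genes, 0 and 1 of the NF-kB genes, 0 and 2 of the ER chaperones, 1 and 1 of the hypoxia genes, 1 and 0 of the cholesterol genes, 0 and 1 of the NRF2 targets, 0 and 3 of the TGF-beta and YAP targets and 1 and 0 of the microRNA pathway proteins. In neither line did any of 9 CDK inhibitors and pocket proteins, 11 immune cell markers or 9 endothelial markers pass, nor did any apoptosis regulator, Wnt target or intestinal marker in the arrays labelled LoVo. Of 37 ribosomal protein genes 1 rose in A549, of 37 oxidative phosphorylation genes 2 rose in A549, of 11 housekeeping genes 1 rose in the arrays labelled LoVo, of 11 lung markers 1 rose in A549 and of 10 fibroblast markers 1 fell in the arrays labelled LoVo. Median, mean and test differed in sign for 8 of these lists in A549 and 6 in the arrays labelled LoVo.

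**Figure D4:**
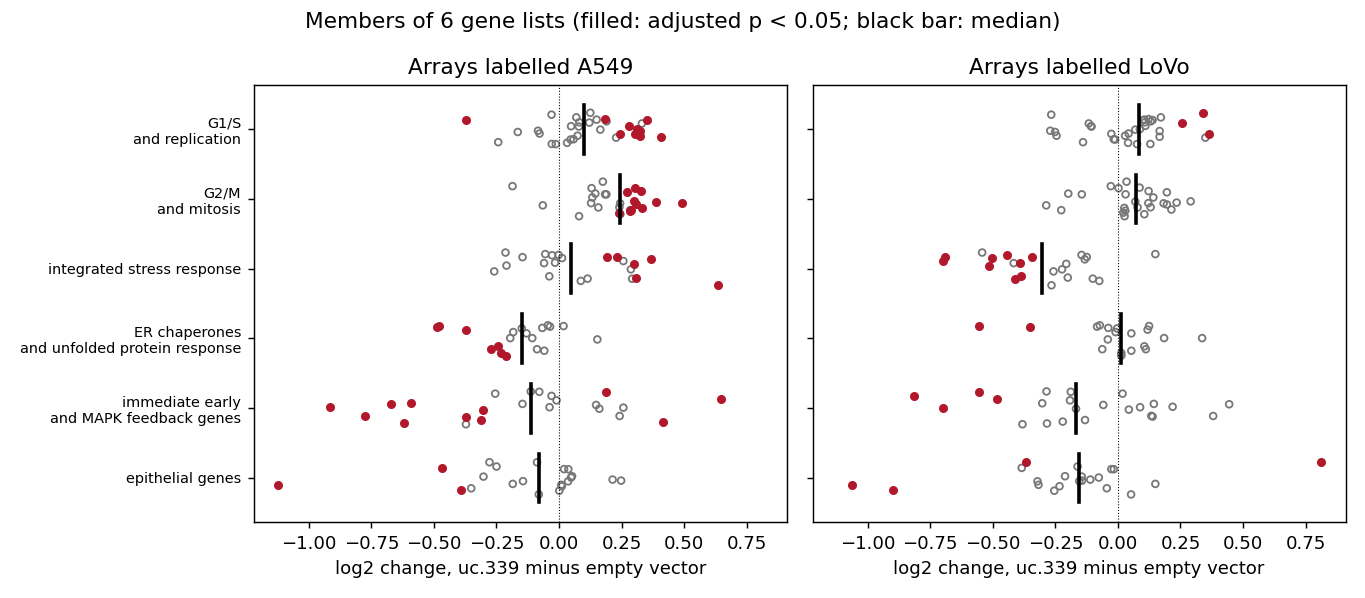
Changes with uc.339 (log2) of the members of 6 gene lists in A549 and in the arrays labelled LoVo; points are genes, filled where the adjusted p passed, and black bars are list medians. The G2/M and mitosis list had a median of 0.24 in A549, and the integrated stress response list -0.30 in the arrays labelled LoVo.

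CCNE2 read higher with uc.339 in both lines without passing the test over all genes. Its brighter probe set read 8.78 ± 0.17 against 8.55 ± 0.18 in A549, a change of 0.23 ± 0.13 (SE; adjusted p = 0.286, limma, n = 3), and 8.75 ± 0.23 against 8.40 ± 0.02 in the arrays labelled LoVo, a change of 0.35 ± 0.13 (adjusted p = 0.139). Its dimmer probe set read 0.71 ± 0.20 in A549 and 0.85 ± 0.20 in the arrays labelled LoVo (limma, adjusted p = 0.0495 and adjusted p = 0.0662 over all probe sets). Both of these rises began at a dim level, 6.05 and 5.74. Within same-numbered pairs the uc.339 array was the higher in 6 of 6, by 0.231, 0.213 and 0.240 in A549 and by 0.402, 0.530 and 0.119 in the arrays labelled LoVo for the brighter probe set. Neither line passed under pairing (adjusted p = 0.153 and adjusted p = 0.12 with replicate number as a block within each line). The difference between the lines, 0.12, did not pass the test (adjusted p = 0.732). Without LoVo uc.339 replicate 3 the LoVo change was 0.48 (adjusted p = 0.0388). With the interquartile range as a covariate, which was partly tied to the A549 arms, the A549 change was 0.45 (adjusted p = 0.013) and the LoVo change 0.18 (adjusted p = 0.463). With the ACTB covariate these were 1.29 and 0.15 (adjusted p = 0.464 and adjusted p = 0.741). With averaged probe sets they were 0.47 and 0.60 (adjusted p = 0.0834 and adjusted p = 0.0683). Without A549 uc.339 replicate 2 or empty-vector replicate 3 the A549 change was 0.14 or 0.15 (adjusted p = 0.593 or adjusted p = 0.581).

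**Figure D5:**
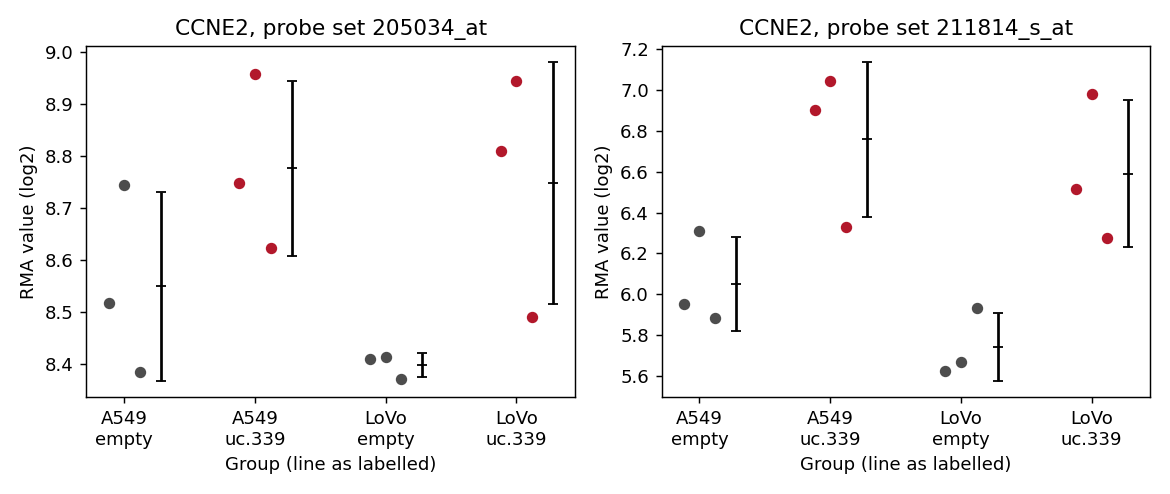
CCNE2 expression (log2) in the 12 arrays for both of its probe sets, with points for arrays and bars for mean ± SD (n = 3); the axes do not start at 0. The brighter probe set averaged 8.78 with uc.339 and 8.55 with the empty vector in A549, and 8.75 and 8.40 in the arrays labelled LoVo.

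Some genes changed the same way in both lines. KRT19, a keratin, fell by 1.12 in A549 and 1.06 in the arrays labelled LoVo, CEACAM1 by 1.69 and 1.37, NTS, neurotensin, by 0.73 and 0.95, CSTA by 1.05 and 0.67 and IFITM3 by 0.64 and 0.61. EFEMP1, a matrix protein, rose by 0.93 and 1.04 (other probe sets 0.02 to 0.62 under LoVo), FRMD6 by 0.67 and 0.74, IL1RAP by 0.63 and 0.49, CAVIN2, a caveolar protein, by 0.45 and 0.70 and ADD2 by 0.39 and 0.41. Other probe sets of IL1RAP went the opposite way in both lines, those of ADD2 did so in the arrays labelled LoVo and read -0.08 to 0.22 in A549. That of CAVIN2 read -0.06 in the arrays labelled LoVo. Averaging probe sets ended the calls of IL1RAP in both lines, ADD2 in A549 and CAVIN2 in the arrays labelled LoVo (adjusted p from 0.0753 to 0.159), and turned ADD2 there to -0.025. In the arrays labelled LoVo IL1RAP read 2.66 and 3.15 with the empty vector and uc.339, and CAVIN2 3.22 and 3.93. These levels were dim in both arms, as were those of EFEMP1, FRMD6 and ADD2 there and of IL1RAP and CSTA in A549. In all, 112 genes were called in both lines, 62 in the same direction, 15 of them dim in both arms of at least 1 line. Of these 20 rose in both (9.10 for independent lists; Fisher's exact test, BH-adjusted p = 0.00114) and 42 fell in both (15.4; adjusted p = 9.88e-09). The opposite directions held 50, also above independent lists: 24 rose in A549 and fell under LoVo (13.8; Fisher's exact test, adjusted p = 0.00749) and 26 the reverse (10.2; adjusted p = 1.82e-05). Both contrasts used 1 variance per gene from the same fit, and genes vary together. Independent lists are thus no exact reference, and these p-values from Fisher's test only describe the overlap. Across genes, which are not independent replicates, the fold changes correlated at r = 0.108, and 48 of 100 splits of the arrays gave an r of that size or more. With replicate number as a block within each line 21 genes were called the same way in both lines. Of the 10 named, CSTA, IFITM3, FRMD6, IL1RAP and ADD2 then lost their LoVo call (adjusted p from 0.0547 to 0.0987). Averaged probe sets gave 38 such genes, and leaving out 1 array gave 21 to 177, the highest without LoVo uc.339 replicate 3.

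The response differed between the lines for genes of several kinds. The lowest value was that of EREG, at -3.17 log2 units (LoVo change minus A549 change, adjusted p = 3.65e-05, limma; other probe set -0.14), with ALDH1A1 at -2.73, ANXA1 at -2.47 (its other probe set 0.36), COL1A2 at -1.83 and EPAS1 at -1.83. TCF4 differed by 3.03 (other probe sets 0.12 to 2.25), EPHA7 by 2.97, TCN1 by 2.20, FCGBP by 2.16 and CEACAM6 by 2.00. Several of these sizes are limited by the range of the arrays. EREG read 2.65 with uc.339 under LoVo, where the lowest value of any probe set was 2.12, and ALDH1A1 read 14.55 and 14.59 in A549, where the highest was 14.93. COL1A2 was dim in both A549 arms, and TCN1, FCGBP and CEACAM6 were dim in both arms under LoVo, which limits the sizes of their differences. Of 22 integrated stress response genes, 11 had a lower response under LoVo and 0 a higher (14 and 0 adjusted over the list alone; median -0.39, adjusted p = 7.86e-10, camera, and adjusted p = 0.00785 with an estimated correlation). ATF3 differed by -0.96, SLC7A11 by -0.53, TRIB3 by -0.52 and ASNS, asparagine synthetase, by -0.51. ATF3 was dim in both A549 arms, which limits the size of its difference. The other probe set of ASNS read 0.03, and averaging the 2 ended its call (adjusted p = 0.277). Of 19 ER chaperone genes, 2 had a higher response under LoVo (6 adjusted over the list alone; median 0.17, adjusted p = 4.76e-05, and adjusted p = 0.0197 with an estimated correlation): DNAJC3 by 0.49 and CRELD2 by 0.35, with HSP90B1 (0.44) and DNAJB9 (0.38) not passing. Of 26 G2/M genes, 0 passed (4 lower adjusted over the list alone; median -0.14, adjusted p = 0.00628, but adjusted p = 0.31 with an estimated correlation), with AURKB at -0.51 (other probe set 0.23), CENPE at -0.32, CDC25C at -0.30 and CCNB2 at -0.26 (other probe sets 0.10 to 0.32). Averaging probe sets ended this list's call (adjusted p = 0.171). With the ACTB covariate the ER chaperone list no longer passed (median 0.21, adjusted p = 0.18), while the integrated stress response (adjusted p = 0.00177) and G2/M lists (adjusted p = 0.0105) did. In that fit the endothelial and intestinal marker lists passed upward too (camera, adjusted p = 0.0367 each), which they did not without the covariate. Most endothelial markers were dim in every group, so passing with this covariate is weak evidence for a list. The differences of AURKB, CENPE, CDC25C, CCNB2, HSP90B1 and DNAJB9 did pass in the brighter genes, with trend and robust eBayes and with array weights (adjusted p from 0.008 to 0.0379). The other 24 lists had adjusted p from 0.176 to 0.966, with 5 differing in sign between median, mean and test; 28 of their members had a higher and 24 a lower response under LoVo (41 and 40 adjusted over the list alone). In all, 992 genes differed, 559 with a higher response under LoVo and 433 with a lower, and 142 by at least 2-fold; 352 were dim in both arms of at least 1 line. With replicate number as a block within each line 564 passed, 515 of them among the 992, and CRELD2 did not (adjusted p = 0.0786). Without A549 empty-vector replicate 1, LoVo uc.339 replicate 1 or LoVo empty-vector replicate 1, 648, 575 or 610 passed, and with the ACTB covariate 0 did, with 1209 at an unadjusted p under 0.05.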

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

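The tests of line identity, the covariates, the share of change in LoVo uc.339 replicate 3, the splits for the correlation of fold changes and the splits that part every pair were chosen only after the result was seen; the other tests were set before it.

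A difference between the lines, tested as an interaction, singled out 992 genes and these values of the LoVo change minus the A549 change in log2 units: EREG -3.17, ALDH1A1 -2.73, ANXA1 -2.47, COL1A2 -1.83, EPAS1 -1.83, TCF4 3.03, EPHA7 2.97, TCN1 2.20, FCGBP 2.16 and CEACAM6 2.00. EREG, TCN1, FCGBP and CEACAM6 were dim in both arms under LoVo and COL1A2 in both A549 arms, and ALDH1A1 was near the top of the range in A549, so these sizes are limited by the range of the arrays. The same interaction singled out the integrated stress response (list median -0.39), ER chaperones (0.17) and G2/M and mitosis genes (-0.14). The ER chaperone call ended with the ACTB covariate (adjusted p = 0.18). The call of the last list, with 0 of 26 members passing, ended with an estimated correlation (adjusted p = 0.31) and with averaged probe sets (adjusted p = 0.171). Of the 32 splits within the lines that part every same-numbered pair, as the real one does, 3 gave 992 genes or more, the real one included (3 of 100 splits drawn without regard to pairs). The highest other count, 2400, came from a split that kept both groupings and swapped the LoVo arms, and 1699 from a split that kept the A549 grouping alone. For the 3 lists, 11 of the 32 splits gave as many, with up to 8 (13 of the 100). Each split with as many genes or lists kept the grouping of at least 1 line, and so held that line's own response. The 18 splits of the 32 that broke both groupings gave at most 0 genes and 2 lists, and are too few for a share under 0.05.

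The first pattern is that the arrays labelled LoVo did not read high for intestinal markers. Against exchanged labels, 0 of 21 NRF2 targets were at least 2-fold higher there, where A549 cells would read them high. Array probes that do not respond stay open for most of the markers: 4 of the 14 intestinal probe sets were at least 4-fold apart between the lines, and these values do not show whether the other 10 respond. Cells other than LoVo stay open too, since the count of 0 of 14 markers at least 2-fold higher is the pattern itself and no test of it. A LoVo culture that had lost these markers was not tested, and stays open. Beyond these markers, 8 of 21 epithelial genes were at least 2-fold lower there and 0 higher by that margin. Among them CDH1 and DSP read 10.45 and 11.24 in A549, so their probe sets do respond, while POSTN read 14.52 in the arrays labelled LoVo. No reference profile of LoVo was compared, so these values do not decide between other cells and a changed LoVo culture. The count of 12647 genes between the lines in the 6 empty-vector arrays was the largest of 10 splits (1 of 10, highest other 0), too few for a share under 0.05.

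The next pattern is the A549 response, which went with a higher ACTB 3′ minus 5′ difference in the empty-vector arrays. If lower 5′ signal were its whole source, other probe sets of the called genes could be expected to move apart; over 1497 genes their median share of the change was 0.447 (quartiles 0.0572 and 0.913), between the bounds set, and 78.2% moved the same way. With the ACTB difference as a covariate 0 genes were called, because the SE rose from 0.0756 to 0.298 while the median change of the 2322 genes went from 0.357 to 0.448; the covariate separates the A549 arms, so RNA quality and uc.339 cannot be told apart by it. In a fit of the A549 arrays alone the real split called 1433 genes and 7 lists, with at most 0 genes and 1 list in the other splits (1 of 10 in both cases). These splits are too few for a share under 0.05, and the 3 others that parted all pairs called 0 genes.

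The last pattern is the LoVo response and its dependence on the spread of single arrays. Against that spread as its whole source, the changes of the 412 genes with the interquartile range as a covariate had a median ratio of 0.891 to those without (quartiles 0.802 and 1.00), the median change going from 0.471 to 0.405 with an SE of 0.0821 and 0.0794. The changes shrank while the SE stayed close. With the covariate 210 genes were called, 190 of them among the 412, and ADD2, CDC6, CSTA, FRMD6, GINS1, IFITM3, IL1RAP and MCM10 were no longer called (adjusted p from 0.0587 to 0.143). The spread may thus account for part of the changes. Empty-vector cells mixed into uc.339 replicate 3 may account for part: over 42 genes called at 2-fold or more without it, that array showed a median share of 0.834 of the change (quartiles 0.561 and 1.01), against 1.01 and 0.958 for replicates 1 and 2 over 27 and 26 genes chosen in the same way. This met the bounds written against mixing. But these are the largest changes alone, and a share below 1 leaves room for a smaller admixture, so it was left open. Replicate 3 also had the lowest interquartile range of its group, 3.44 against 3.51 and 3.54. A549 uc.339 replicate 3 did too, at 3.38 against 3.47 and 3.50. The share thus cannot tell mixing from spread. The shares of replicates 1 and 2 were taken against changes that include replicate 3, which may raise them. In a fit of the arrays labelled LoVo alone the real split called 149 genes and 5 lists. The others gave at most 0 and 1 (1 of 10 in both cases), too few splits for a share under 0.05. The 3 others that parted all pairs called 0 genes. An effect of uc.339 in these cells stays among the open explanations.

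For the 62 genes called the same way in both lines, 1 of the 32 splits that part every pair gave as many (the real one; highest other 50, with the LoVo arms swapped), as did 1 of the 100. The other 30 splits broke the grouping of at least 1 line and held 0 shared calls, and the 18 that broke both are too few for a share under 0.05. A shared call needs calls in both lines, so splits that break a grouping could hardly give any. The shares of 32 and of 100 are thus no measure of chance, and the comparison left is 62 against 50 with the LoVo arms swapped. Leaving out 1 array gave 21 to 177, the highest without LoVo uc.339 replicate 3. The correlation of 0.108 was equalled or passed by 48 of 100 splits, up to 0.444, so chance is not excluded for it.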

How the results depend on the processing

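The fits with a covariate were chosen after seeing the data; the other alternatives were planned. Of 2910 values for named genes under alternatives, 2619 kept their direction and side of the threshold, 230 lost the call, 56 gained it and 5 reversed; of 381 for gene lists, 335 stayed and 46 lost the call. The cause was not tested except where stated. Levels were dim in both arms for 331 of the 2322 A549 calls and 79 of the 412 LoVo calls, which limits their sizes.

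The A549 count of 2322 became 1433 with the arrays of that line alone (fewer arrays), 4228 with every probe set, 88 at 2-fold or more and 900 at an adjusted p under 0.01. It became 3540 with the interquartile range as a covariate, which was partly tied to the A549 arms. The LoVo count of 412 became 1302 in the brighter genes, 1273 with trend and robust eBayes, 3663 with array weights, 149 with that line alone, 28 at 2-fold or more, 127 at an adjusted p under 0.01 and 210 with the interquartile range. The difference of 992 became 1627 with trend and robust eBayes, 2211 with array weights, 2041 with every probe set, 142 at 2-fold or more, 344 at an adjusted p under 0.01 and 542 with the interquartile range. The baseline count became 8284 in the brighter genes (fewer genes tested). Genes called the same way in both lines became 297 in the brighter genes, 38 with averaged probe sets, 257 with trend and robust eBayes and 500 with array weights.

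With the ACTB 3′ minus 5′ covariate, which separates the A549 arms and widens the SE, A549, the difference and the shared calls fell to 0 genes, LoVo to 110, the baseline to 3929 and A549 lists to 1; 81 of 112 named-gene calls were lost. The correlation of fold changes turned to -0.0117, the CCNE2 difference to -1.14 and the AURKB difference to 0.016.

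With replicate number as a block within each line the counts were 1382 in A549, 167 in LoVo, 564 for the difference and 21 shared; with a block over both lines they were 2219, 381 and 955. Beyond the calls named in the results, this second block ended those of JUP, GINS1, IL1RAP and MCM10 (adjusted p from 0.0578 to 0.0667) and of the LoVo immediate early list (0.0501), and the blocks changed no other call of a named gene or list.

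Calls of PDIA4 in A549 and of ADD2, CDC6, CEBPB, DNAJA1, DUSP5, FRMD6, GINS1, IFITM3, IL1RAP, KRT18, MCM10 and SLC7A11 in LoVo ended with that line alone (adjusted p from 0.0544 to 0.134), JUP in A549 and CSTA and GINS1 in LoVo with cyclic loess (up to 0.0618), and CXCL5 in A549 with the interquartile range (0.065). Gains beyond those in the results were NFKBIA in A549 (3 settings, up to 0.0455) and the CDC25C, CENPE and HSP90B1 differences (up to 0.0481), and without 1 array HSPA4 in LoVo and the AURKB, CDC25C, DNAJB9 and HSP90B1 differences (up to 0.0476).

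A549 lists numbered 3 with the interquartile range and 3 with an estimated correlation, and LoVo lists 2 in the brighter genes and 1 with an estimated correlation. CCNE2 in A549 was 0.45 with the interquartile range and 0.71 in its other probe set, both passing, and in LoVo 0.38 with array weights, passing. The correlation of fold changes was 0.229 in the brighter genes. ADD2 in LoVo turned to -0.025 and the CCNB2 difference to 0.056 with averaged probe sets, and the CCNE2 difference to -0.27 with the interquartile range.

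Leaving out 1 array (the pair left is assumed to vary like the other groups) gave 1354 to 2503 genes in A549, the lowest without empty-vector replicate 1 (uc.339 replicates 1 and 2 gave 1449 and 1460, empty-vector replicate 3 1408). It gave 139 to 1347 in LoVo, the highest without uc.339 replicate 3 (uc.339 replicates 1 and 2 gave 140 and 161, empty-vector replicates 1 and 2 146 and 139, A549 empty-vector replicate 1 257). It gave 575 to 1115 for the difference (648 without A549 empty-vector replicate 1, 575 and 610 without LoVo uc.339 and empty-vector replicate 1) and 21 to 177 shared genes, the highest without LoVo uc.339 replicate 3 (A549 uc.339 replicates 1 and 2 gave 39 and 32, A549 empty-vector replicates 24, 36 and 29, LoVo uc.339 replicates 1 and 2 21 and 29, LoVo empty-vector replicates 1 and 2 23 and 22). A549 lists ranged from 4 (without empty-vector replicate 2) to 7, LoVo lists from 1 (without uc.339 replicate 3) to 7, and the correlation from 0.0284 to 0.186. CCNE2 ranged from 0.137 to 0.326 in A549 (0.137 without uc.339 replicate 2, 0.145 without empty-vector replicate 3 and 0.326 without empty-vector replicate 2) and from 0.252 to 0.479 in LoVo, the highest without uc.339 replicate 3.

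Leaving out 1 array ended the calls of CAVIN2, CXCL5, FRMD6, JUP, MUC13 and PDIA4 in A549 (for 2 to 7 of the 12 arrays, adjusted p up to 0.143) and of ADD2, CDC6, CEBPB, CSTA, DNAJA1, DUSP5, FRMD6, GINS1, IFITM3, IL1RAP, KRT18, MCM10 and S1PR1 in LoVo (for 1 to 11 arrays, adjusted p up to 0.176). In A549 it ended the NF-kB (0.0568) and immediate early (0.0526) lists without empty-vector replicate 2, the epithelial list without that array or uc.339 replicate 2 (up to 0.0621) and the intestinal list without uc.339 replicate 2 or empty-vector replicate 3 (up to 0.0627). In LoVo all lists but the integrated stress response ended without uc.339 replicate 3 (adjusted p from 0.0528 to 0.111).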

Other observations

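The lists of mucus secretory genes and of EGF receptor ligands were written after the named genes were seen and before the values of their members. An exception is TFF3, which was also in the intestinal list tested before. The tests of CCNE2 over both lines were chosen only after the result was seen.

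Beyond the mucins named in the results, some genes of mucus-secreting epithelium fell in A549 with uc.339. Of 33 other such genes, 0 rose, 10 fell and 23 did not pass. Among the 23, SPDEF read -0.35 (limma, adjusted p = 0.0524) and ERN2 0.07. MUC2, TFF3 and ATOH1 read 0.03, 0.16 and 0.05, at dim levels in both arms. The transcription factors FOXA3 and CREB3L1 fell by 1.20 and 0.55, the secretory disulfide isomerases AGR2 and AGR3 by 0.74 and 1.25, and the trefoil factor TFF1 by 1.40. The membrane mucins MUC16 and MUC1 fell by 1.32 and 0.41, and the secreted defence proteins LCN2, SLPI and BPIFB1 by 1.40, 1.25 and 0.97. AGR3 and MUC16 were dim in both arms, and the falls of TFF1, BPIFB1 and CREB3L1 ended at a dim level, so their sizes are limited. The list median was -0.14 and its mean -0.34 (camera p = 1.82e-06; p = 0.0133 with an estimated correlation). A broader fall of the secretory programme is a hypothesis that this test fits, subject to the ACTB difference between the A549 arms.

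A broader fall of EGF receptor ligands under the LoVo label, beyond EREG and BTC, could not be decided. HBEGF read -0.23, EGF -0.21 and TGFA 0.08, none passing. The other 3 of the 6 genes in the list were neuregulins, which bind other receptors of the family; NRG1 rose by 0.97 (adjusted p = 1.37e-05, limma), and NRG2 and NRG4 read -0.01 and 0.14. EGF, TGFA, NRG2 and NRG4 were dim in both arms there. The direction of the list was upward, with NRG1; the p from camera, a test in limma over all genes, was 0.171. This met the bound first written against a broader fall, but with 3 of 6 members neuregulins it is no test of the ligands of the EGF receptor itself.

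CCNE2, which passed in neither line over all genes, was tested over both lines at once. Its mean change was 0.29 log2 units in the brighter probe set (two-sided exact permutation p = 0.025 within lines) and 0.78 in the dimmer (p = 0.005, the smallest that 400 regroupings can give). Exchanging the arms within same-numbered pairs gave a two-sided exact permutation p = 0.031 for each probe set, the smallest that 64 exchanges can give. CCNE2 was named before the data were seen, but from prior knowledge of the study that made these arrays. The choice of this gene is therefore not independent of them. The tests over both lines were also chosen after its values were seen on the same arrays. A small rise of CCNE2 in both lines thus stays a hypothesis.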
